A study of Schizosaccharomyces pombe with 19 samples.

How the data were processed

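The series measured where histone H3 dimethylated on lysine 9 (H3K9me2, the mark of heterochromatin) and 4 tagged cohesin subunits lie along the genome of Schizosaccharomyces pombe, by chromatin immunoprecipitation (ChIP) on 2-colour tiling arrays. Cohesin is the ring complex that holds sister chromatids together. Rad21 is its mitotic kleisin, and Psc3 is an accessory subunit of both mitosis and meiosis. Rec8 and Rec11 are normally expressed in meiosis. Of the 19 arrays, 3 measured H3K9me2, 6 Psc3-GFP, 2 Rad21-GFP, 6 HA-Rec8 and 2 Rec11. ChIP DNA was labelled with Cy5 and whole-cell extract DNA with Cy3, per the labels. Cells were grown at 30 °C and, for the cohesin arrays, held at 18 °C for 2 h before fixation in 3% paraformaldehyde.

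The arrays held 42968 spots, of which 41551 were probes rather than controls, spaced 300 bp apart. Spots were quantified by the authors with Agilent Feature Extraction, version 11.5.1.1 or 12.0.3.1, per the file headers. The deposited red and green processed signals are intensity values that the software had background-subtracted and dye-normalized, by a method the headers do not give. They had not been normalized between arrays. Background-subtracted signals and pixel medians are also deposited as intensity. The deposited log ratio of each spot is a log10 value of red over green. In the value table deposited with the series, 6 of 19 columns hold log2 ratios that match the scanner values. Another 2 columns of that table, deposited for Rec11, are on a log2 scale as far as their spread shows, and 11 columns deposited by the authors hold a linear ratio with medians between 0.97 and 1.02. Those 13 columns do not match the scanner values position by position, with r between -0.0063 and 0.0248, so the table was not used for any fit.

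The value analysed was the log2 of red over green processed signal minus the array's median. It correlated with the deposited log ratio at 0.998 or above on every array. Spots flagged as outliers, between 0 and 213 per array, were set to missing. Median signals lay between 966 and 1268 in green and between 943 and 1276 in red. At least 99.9% of spots were well above background and 0 were saturated. Probes were averaged in windows of 1.5 kb with at least 2 probes, which gave 8326 windows. Another 72 probes were left out because a block of DNA was missing from the extract of at least 1 array.

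The header does not name the genome build. The GC content of the reference sequence at the probes' positions was compared with the extract signal in 9 chromosome segments. The best match lay at shifts from -1660 to 3980 bp, within 100 bp of 0 in only 1 segment, and 1 probe lay beyond the end of the reference chromosome. Positions are therefore given in the array's own coordinates, with no gene names taken from position. Windows therefore took the place of genes as the units tested and named. The gene lists and the classes of intergenic DNA fixed beforehand were not run, because both need gene positions of the array's build.

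Chromosome domains were set from the repeat marks in the probe names and the extract signal, in place of the reference features fixed beforehand. A repeat block had repeat marks on at least 50% of 11 neighbouring probes, with gaps up to 12 kb joined. The central core of a centromere was the part of the block whose extract signal stayed below -1 (running median over 5 probes), and it may include the innermost repeats. It held 102 probes in all, 33 of them without a repeat mark. Centromere flanks were the 50 kb on either side, and subtelomeres the outer 50 kb of chromosomes 1 and 2. The ends of chromosome 3, which border ribosomal DNA, the mating-type region on its own contig, and 129 probes of telomere clones were kept apart. Chromosome arms were the rest. Arm sites of cohesin were the 518 arm windows at or above a log2 ratio of 1 on the wild-type Rad21 array, a definition chosen after the data were seen.

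Windows were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with Benjamini-Hochberg adjustment over all windows and a threshold of 0.05. The 6 Rec8 arrays, 2 per group, were fitted together. In the Psc3 fit only the wild type had 2 arrays, so each lone mutant array was assumed to vary like the wild-type pair. Nothing in the labels says that replicates are separate cultures, so p-values may measure technical spread only. H3K9me2, Rad21 and Rec11 had 1 array per group and no test. With 2 arrays against 2, the smallest p that a two-sided exact permutation test of a domain mean can give is 0.333, so domain means are given as values with their SD. The Rec8 replicate number also marks the antibody clone and the slide. Deviations from the group means correlated across 8326 windows at 0.16, 0.15 and 0.17 between arrays of the same number, and the replicate number as a block was an alternative. Pairs of mutant and wild-type arrays from the same slide exist for all sets except Psc3 clr4Δ, dcr1Δ and mmi1Δ rec8Δ. Those mutants were hybridised on slides without a wild-type array, so slide and strain cannot be separated there.

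Groups, tests, alternatives and the naming rule were fixed before the data were examined, the rule for genes, and were applied to windows. For a tested comparison the rule took the 10 largest rises and the 10 largest falls among called windows whose every replicate difference had the same sign. For 1 array against 1 it took the 10 largest differences each way among windows with at least 3 probes, all of which differed in that direction. For each target it took the 10 highest wild-type windows. Simulated data with the same layout were used to test the fits. Of 100 changed windows, the Rec8 fit (8326 windows) recovered 48% of changes of 0.5 and 100% of changes of 1, with 6 unchanged windows called. The Psc3 fit (8321 windows) recovered 56% of changes of 1 and 100% of changes of 2, with 9 unchanged windows called. The simulated arrays all varied alike within a window and held no slide effect. They therefore could not check whether lone mutant arrays vary like the wild-type pair.

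The alternatives fixed with them were normexp background correction with an offset of 50, scaling of each array by its median absolute deviation (MAD), leaving out dim probes, the median over probes, at least 3 probes per window, the replicate block, a fit of only the groups compared, a joint fit of the Psc3 and Rec8 arrays, another H3K9me2 threshold, subtelomeres of 100 kb and leaving out each replicate in turn. The series value table, also fixed beforehand, was run only for H3K9me2, where its columns match the scanner values. Centring on arm probes, leaving out repeat-marked probes and using background-subtracted signals were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.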

Results

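The 19 arrays fell into 15 groups, 4 of them with 2 arrays (Psc3 in wild type, and HA-Rec8 in wild type, in mmi1Δ and under rec8 overexpression) and 11 with 1 array. Values are log2 ratios of ChIP over whole-cell extract, centred on each array's median. Most means of groups with 2 arrays are given with the SD and n. All values of the 11 other groups come from 1 array and have no replicate. Positions are in the array's own coordinates, whose genome build is not named. The genome was read in 8326 windows of 1.5 kb, of which 56 lay in the pericentromeric repeats and 21 in the central cores, the part of a centromere where kinetochores assemble. Over the 4 replicate pairs the pooled SD of a domain mean was 0.29 in the central cores, 0.18 in the repeats, 0.04 in the flanks, 0.03 in the subtelomeres and 0.12 in the mating-type region.

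In wild-type cells H3K9me2, Psc3 and Rad21 were highest in heterochromatin. The 10 highest windows of Psc3 and the 10 highest of Rad21 all lay in the pericentromeric repeats, where they reached 4.84 and 3.89. H3K9me2 was highest at a repeat window of chromosome 3 (1134000 to 1135200), at 5.97, and its 10 highest windows were 5 in the repeats, 4 in the subtelomeres and 1 in the mating-type region. The mean over the repeats was 5.12 for H3K9me2, 4.02 ± 0.04 (SD, n = 2) for Psc3 and 3.31 for Rad21. Rec8, whose gene is normally expressed in meiosis, stood at 0.52 ± 0.16 (SD, n = 2) there, and its 10 highest wild-type windows, between 1.05 and 1.34, all lay at the ends of chromosome 3. In the central cores H3K9me2 stood at 4.38, while Psc3 was at 0.58 ± 0.07 (SD, n = 2), Rad21 at 0.49 and Rec8 at 0.62 ± 0.28 (SD, n = 2).

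**Figure D1:**
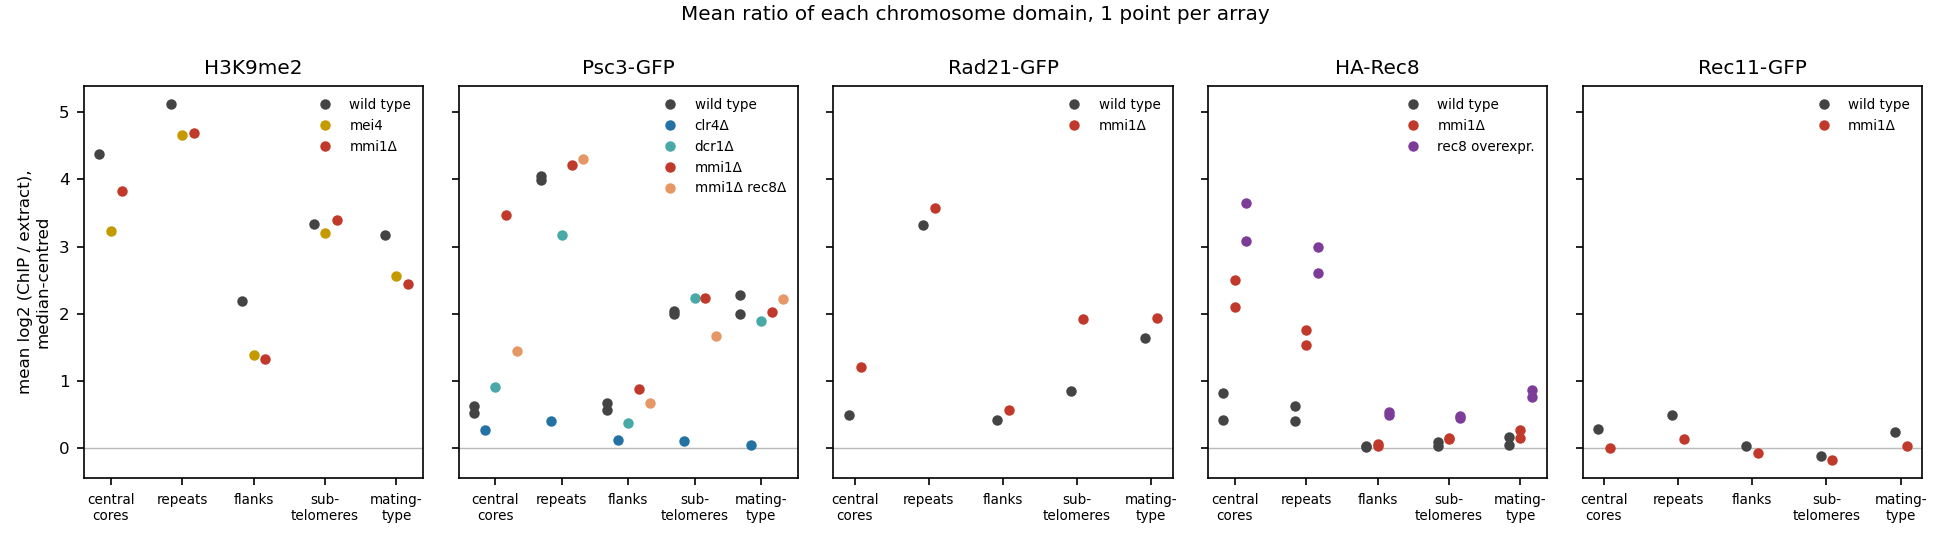
Mean log2 ratio of ChIP over extract, median-centred (vertical axis), in 5 chromosome domains (horizontal axis) for each target, with 1 point per array and colours for strains; "repeats" are the pericentromeric repeats, and mmi1Δ of Rad21 follows the label. In the central cores Psc3 stood at 3.46 in mmi1Δ against a wild-type mean of 0.58, and Rec8 at group means of 0.62, 2.30 and 3.37 in wild type, mmi1Δ and rec8 overexpression.

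The deleted genes were read from the extract channel. A block of chromosome 2 (457800 to 458700) was lost from the extract of the clr4Δ array, at -7.29 relative to the other arrays. The dcr1Δ array had lost a block of chromosome 3 (1507200 to 1510800), at -8.52, and the mmi1Δ rec8Δ array a block of chromosome 2 (2571300 to 2571900), at -7.36. A block of chromosome 3 (337800 to 339300) was lost from 6 of the 7 arrays labelled mmi1Δ. On the Rad21 array labelled mmi1Δ it stood at -1.18 in the extract, against -0.80 to 0.14 on the 12 arrays without the label, and at -2.74 in the ChIP channel. That array is therefore called by its label throughout. Per the labels, the mmi1Δ strains of the Psc3, Rad21 and Rec8 sets also carry a mei4 mutation, which the arrays cannot show.

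The comparison of Rec8 in mmi1Δ and wild type asks where Rec8 goes in vegetative cells that lack Mmi1, the protein that removes meiotic transcripts during vegetative growth. In mmi1Δ, Rec8 was higher at all 3 centromeres. The mean over the central cores was 2.30 ± 0.28 (SD, n = 2) against 0.62 ± 0.28 (SD, n = 2) in wild type, a 3.19-fold difference in the ratio to the extract. Over the pericentromeric repeats it was 1.65 ± 0.15 (SD, n = 2) against 0.52 ± 0.16 (SD, n = 2). At the 518 Rad21 sites of the chromosome arms Rec8 stood at 0.59 ± 0.03 (SD, n = 2) against 0.04 ± 0.01 (SD, n = 2). The centromere flanks, at 0.04 and 0.03, differed by less than the spread between replicates. The same difference in the cores was 1.68 within the slide of replicate 1 and 1.67 within that of replicate 2, each larger than the replicate SD.

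By limma, 1775 of 8326 windows passed for Rec8 in mmi1Δ, 1141 higher and 634 lower. All 21 windows of the central cores and 51 of 56 repeat windows rose. Of the 518 arm sites, 384 (74.1%) rose, against 640 (8.75%) of the 7316 other arm windows. At the ends of chromosome 3, 12 of 64 windows fell, and in the mating-type region 7 of 27 rose and 3 fell. The largest rise lay in the core of centromere 2 (1623000 to 1624200), by 2.42 with a standard error of 0.21 and an adjusted p of 1.42e-05 by limma. Of the 10 largest rises, 7 lay in central cores (1.77 to 2.42) and 3 in repeats (1.91 to 1.96). The 10 largest falls all lay in the arms (-0.92 to -0.69), the largest on chromosome 2 (1266000 to 1267200). They started from wild-type means between -0.23 and 0.79. Of the 518 arm sites, where wild-type Rec8 stood at 0.04, 0 fell. The lower windows therefore do not show a loss of Rec8 from the arm sites of cohesin. The number of lower windows depended more on single arrays than that of higher ones. Without wild-type replicate 1 or 2 the count was 884 (698 higher, 186 lower) and 809 (635 and 174), and without mmi1Δ replicate 1 or 2 it was 1070 (749 and 321) and 691 (572 and 119). It was 2349 (1368 and 981) with the replicate number as a block, 2233 (1320 and 913) with only the 2 groups fitted and 1334 (944 and 390) with the median over probes. The mean difference over the repeats was 1.13, and 0.67 over the 7 of 219 probes without a repeat mark.

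Overexpression of rec8 asks whether more Rec8 alone gives the same pattern in cells that keep Mmi1. Both overexpression arrays had also lost a block in the left flank of centromere 1 (3740100 to 3744000), at -7.79 and -7.67 in the extract. They kept a block of chromosome 3 (115500 to 116700) that the wild-type and mmi1Δ Rec8 arrays had lost. Other strain differences therefore cannot be separated from the amount of Rec8. Overexpression put Rec8 in the central cores at 3.37 ± 0.41 (SD, n = 2), a 6.69-fold difference from wild type in the ratio to the extract. In the repeats Rec8 stood at 2.80 ± 0.27 (SD, n = 2). The arm sites stood at 0.76 ± 0.05 (SD, n = 2). Unlike mmi1Δ, overexpression also gave a higher mean than wild type in the centromere flanks (0.51 ± 0.03, SD, n = 2, against 0.03). In the subtelomeres it stood at 0.46, with 0.14 in mmi1Δ and 0.06 in wild type, and in the mating-type region at 0.82, with 0.21 and 0.10. By limma, 2512 windows passed, 1565 higher and 947 lower. All 21 core and all 56 repeat windows rose, as did 106 of 196 flank windows, 65 of 128 subtelomeric windows, 15 of 27 windows of the mating-type region and 465 (89.8%) of the 518 arm sites. The largest rise lay in the same window of the core of centromere 2 (1623000 to 1624200), by 3.49 (standard error 0.21; adjusted p 4.9e-08 by limma). Among the 10 largest falls were 9 arm windows (-1.12 to -0.72) and 1 window at an end of chromosome 3. Of the 518 arm sites 0 fell, as in mmi1Δ. Without wild-type replicate 1 or 2 the count was 1534 (1145 higher, 389 lower) or 1330 (1043 and 287), and without overexpression replicate 1 or 2 it was 2417 (1527 and 890) or 1846 (1248 and 598). With the replicate number as a block it was 3083 (1770 and 1313), with MAD scaling 1859 (1200 and 659) and with the median over probes 2069 (1381 and 688).

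The direct test between mmi1Δ and rec8 overexpression asks whether the 2 ways of expressing Rec8 place it alike. The strains also differ at the blocks named above, and the mmi1Δ strain carries a mei4 mutation per the labels. By limma, 450 windows differed, and in 383 of them Rec8 was lower in mmi1Δ. The lower windows were 93 of 196 in the flanks, 51 of 56 in the repeats, 19 of 21 in the central cores, 50 of 128 in the subtelomeres and 14 of 27 in the mating-type region. At the arm sites 55 of 518 were lower. The mean difference was -0.47 in the flanks, -1.15 in the repeats and -1.07 in the cores. The largest fall lay in a repeat window of centromere 1 (3753000 to 3754200), at -1.85 from an overexpression mean of 3.18 (adjusted p 1.11e-06 by limma). Among the 67 windows higher in mmi1Δ the largest difference, 0.80, lay on the arm of chromosome 2 (4329000 to 4330200; adjusted p 0.00293 by limma). With the replicate number as a block 748 windows passed (173 higher in mmi1Δ), and with scaling by MAD 136 (12 higher). Without mmi1Δ replicate 1 or 2 the count was 257 (14 higher) or 214 (4 higher), and without overexpression replicate 1 or 2 it was 546 (122 higher) or 325 (27 higher). The difference in the cores did not hold under every setting. It was -0.31 with normexp, -0.42 with MAD scaling, and of the 21 core windows 4 and 0 passed limma, with 1587 and 1111 of all windows below an unadjusted p of 0.05. Without mmi1Δ replicate 2, 6 of the 21 core windows passed, and without overexpression replicate 1, 14. The extract signal of the cores was 1.27 and 1.31 above wild type on the mmi1Δ arrays and 0.24 and 0.20 above it on the overexpression arrays. Their ChIP signal was 2.92 and 2.96 above wild type in mmi1Δ and 3.02 and 2.80 in overexpression. The core difference between mmi1Δ and overexpression therefore lay in the extract channel. The ChIP values do not show more Rec8 in the cores under overexpression.

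**Figure D2:**
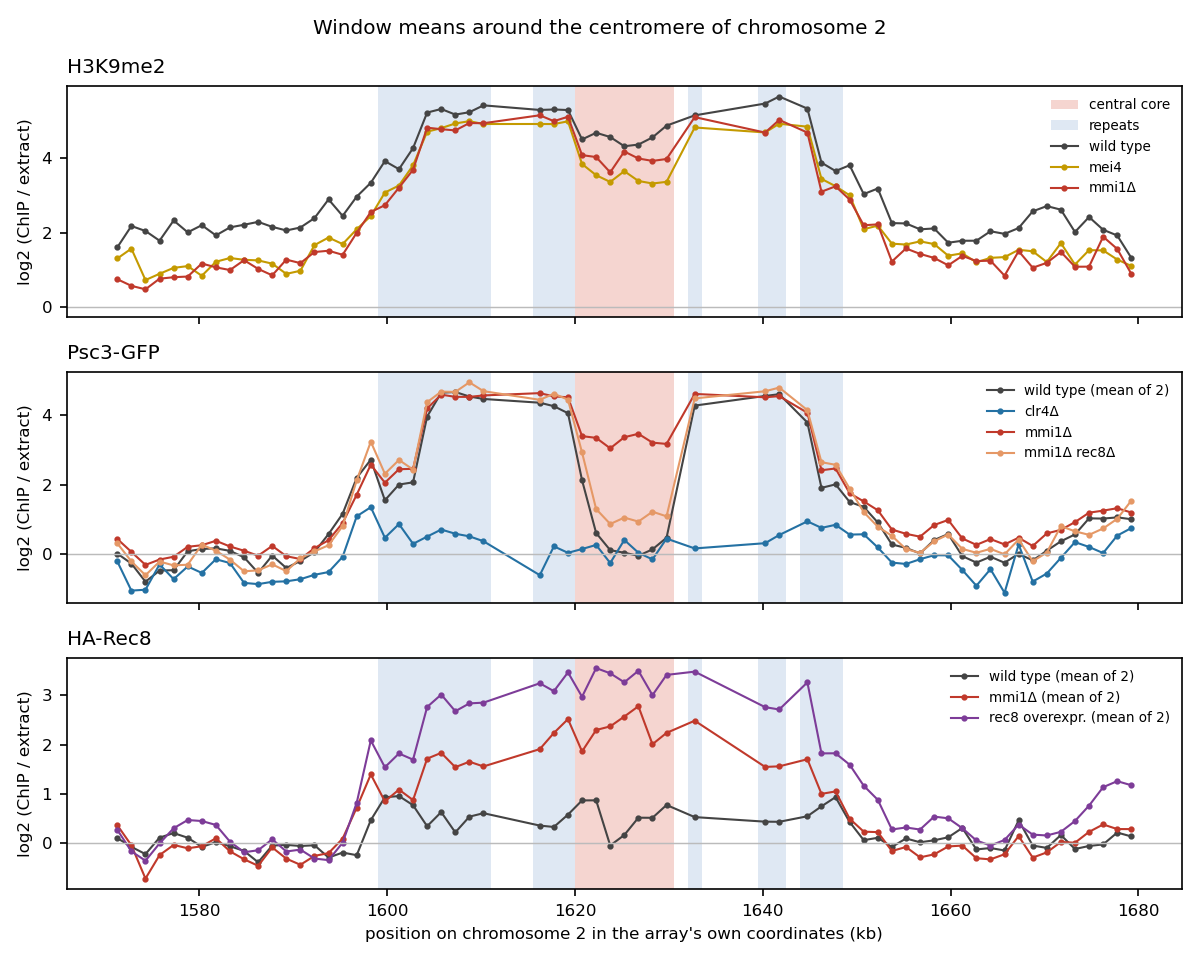
Window means of the log2 ratio of ChIP over extract (vertical axis) around the centromere of chromosome 2 in the array's own coordinates (horizontal axis, kb), with lines for strains and shading for the central core and the repeats. H3K9me2 spans core and repeats, and wild-type Psc3 dips in the core where the mmi1Δ array stays high. The Rec8 ratio is higher in mmi1Δ and higher still under overexpression. The ChIP signal of the cores alone was alike in both, at 2.92 and 2.96 above wild type in mmi1Δ and 3.02 and 2.80 under overexpression.

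Psc3 in clr4Δ addresses whether cohesin at heterochromatin needs Clr4, the H3K9 methyltransferase. In clr4Δ, Psc3 was lower over the repeats, the subtelomeres and the mating-type region. It stood at 0.40 in the pericentromeric repeats against 4.02 ± 0.04 (SD, n = 2) in wild type, at 0.10 in the subtelomeres against 2.02 ± 0.02 (SD, n = 2), and at 0.05 in the mating-type region against 2.14 ± 0.21 (SD, n = 2). At the arm sites it stood at 1.13, against 1.14 ± 0.20 (SD, n = 2), a difference smaller than the replicate spread. By limma, 238 of 8321 windows passed, 213 lower and 25 higher. The falls took in all 54 repeat windows tested, 95 of 128 in the subtelomeres, 18 of 27 in the mating-type region and 11 of 196 in the flanks. Of the 518 arm sites, 10 fell. The largest fall lay in the repeats of centromere 2 (1615500 to 1616700), at -4.96 from a wild-type mean of 4.36 (standard error 0.28; adjusted p 5.49e-13 by limma). The largest subtelomeric fall, on chromosome 1 (5572500 to 5573700), was -4.38, and the largest in the mating-type region (31500 to 32700) was -4.37. The 25 higher windows all lay in the arms, with the 10 largest rises between 1.09 and 1.55. The largest, on chromosome 3 (967500 to 968700), was 0.42 and did not pass with the median over probes. The subtelomeric difference of -1.91 was -1.16 with subtelomeres of 100 kb.

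The count for clr4Δ and its split depended on the fit. In a joint fit with the Rec8 arrays, which leaves the differences as they are and changes the spread, it was 564 (187 higher, 377 lower). Without wild-type replicate 1 or 2 it was 1327 (594 and 733) or 1260 (561 and 699), where the wild-type value changes as well and the spread comes from the Rec8 arrays. Without repeat-marked probes, with 8055 windows tested, it was 93 (20 and 73).

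The dcr1Δ array addresses whether Psc3 needs RNA interference, in which Dcr1 is the Dicer ribonuclease. Psc3 stood at 3.17 in the repeats, a difference of -0.85 from wild type, and at 2.24 in the subtelomeres and 1.88 in the mating-type region, where wild type had 2.02 and 2.14. Measured on the same slide, clr4Δ minus dcr1Δ was -2.77 in the repeats and -2.13 in the subtelomeres. By limma, 9 windows passed. Of these, 4 repeat windows fell (-1.52 to -1.38), 3 subtelomeric windows rose (1.44 to 1.48) and 2 arm windows rose (1.37 to 1.41). The lowest lay at the right edge of centromere 1 (3784500 to 3785700), at -1.52 from 4.45 (adjusted p 0.0335 by limma). No call held under every setting. By limma the count was 0 with normexp (240 windows below an unadjusted p of 0.05), 0 with centring on arm probes (467) and 0 with background-subtracted signals (367), while MAD scaling gave 12 higher and 37 lower windows in place of 5 and 4. The median over probes gave 44 windows, unmarked probes 15 and a joint fit with the Rec8 arrays 152, and without wild-type replicate 1 or 2 the count was 573 (231 higher, 342 lower) or 1140 (476 and 664).

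Psc3 in mmi1Δ asks whether this accessory subunit follows Rec8 to the centromere core. It stood at 3.46 in the central cores against 0.58 ± 0.07 (SD, n = 2) in wild type, a 7.41-fold difference. Against the wild-type array of its own slide the difference was 2.94, with an extract signal 1.07 higher and a ChIP signal 4.01 higher. The pericentromeric repeats differed from wild type by 0.19, about the pooled replicate SD, and the subtelomeres by 0.21. At the arm sites Psc3 stood at 0.74, against 1.14 ± 0.20 (SD, n = 2), a difference of -0.41 that was 0.031 with MAD scaling. By limma, 23 windows passed. All 21 core windows rose, as did 1 window at an end of chromosome 3. The largest rise lay in the core of centromere 1 (3771000 to 3772200), from a wild-type mean of 0.21 to 3.81 (adjusted p 3.45e-09 by limma). In this fit 1 window fell, on chromosome 2 (1474500 to 1475700), at -1.72 from 1.68 (adjusted p 0.000678 by limma). With MAD scaling 305 windows passed and the core difference was 4.67. Unmarked probes gave 8 windows and the joint fit 23 higher and 10 lower. Without wild-type replicate 1 the count was 609 (223 higher, 386 lower) and without replicate 2 it was 485 (280 and 205).

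Removing rec8 from mmi1Δ cells asks whether Psc3 in the core depends on Rec8. In mmi1Δ rec8Δ, Psc3 stood at 1.44 in the central cores, a difference of -2.02 from the mmi1Δ array and of 0.87 from the wild-type mean. By limma, 17 of 21 core windows fell relative to mmi1Δ among 43 called windows, with 1 array against 1 and the spread of the wild-type pair. The 2 arrays come from different slides, so the adjusted p-values by limma cannot separate strain from array or slide. The largest fall lay in the core of centromere 1 (3769500 to 3770700), at -3.11 from 3.64 (standard error 0.32; adjusted p 2.06e-06 by limma). The repeats, at 4.30, stood 0.09 above mmi1Δ. Outside the centromere, 22 subtelomeric windows fell and 4 windows at the ends of chromosome 3 rose (1.46 to 1.53). Those 4 rises were lost with background-subtracted signals and with MAD scaling, which put 2 of them below 0. Under MAD scaling 220 windows passed and the core difference was -3.77, while unmarked probes gave 26 windows and the joint fit 73.

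Against wild type, the mmi1Δ rec8Δ array had 24 called windows by limma, 9 higher and 15 lower. A single core window rose, on chromosome 3 (1095000 to 1096200), by 2.17 (adjusted p 6.02e-05 by limma). Of the 21 core windows, 8 were called with MAD scaling, 8 each without wild-type replicate 1 or 2, and 4 with the median over probes. At the ends of chromosome 3, 8 windows rose (1.32 to 1.54), and the telomere clones stood at 2.97 against 1.81 ± 0.36 (SD, n = 2). All 15 falls were subtelomeric. The 10 largest (-2.79 to -1.85) lay between 5538000 and 5552700 on chromosome 1, the largest at 5548500 to 5549700 from a wild-type mean of 2.98. MAD scaling gave 40 higher and 18 lower windows in place of 9 and 15. Unmarked probes gave 15 windows, background-subtracted signals 15, the median over probes 44, the joint fit 96, and leaving out wild-type replicate 1 or 2 gave 949 (466 higher, 483 lower) or 889 (482 and 407).

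The H3K9me2 arrays ask where heterochromatin depends on Mmi1 and on Mei4, a meiotic transcription factor. All 56 repeat windows and all 21 core windows were at or above a log2 ratio of 1 on each of the 3 arrays, as were 127 of 128 subtelomeric windows in wild type and 126 in each mutant. In the arms and flanks the mutants had fewer marked windows. In the arms 354 windows reached 1 in wild type, 145 in mei4 and 150 in mmi1Δ, of which 133 and 135 were shared with wild type. In the flanks the counts were 194, 144 and 140 of 196. At the ends of chromosome 3 the order depended on the threshold, with 18, 22 and 20 of 64 windows at 1 and 17, 9 and 6 at 1.5. Mean ratios were lower in both mutants in the flanks, at 1.38 and 1.33 against 2.19, and in the mating-type region, at 2.56 and 2.44 against 3.18. Over the whole genome 793, 534 and 532 windows reached 1, and 1304, 1051 and 1021 reached 0.5. At 1.5 the counts were 578, 318 and 329. The arrays also differed in the range of their ratios. The SD over probes was 0.92 in wild type and 0.80 in each mutant, and the mitochondrial genome stood at -4.65, -4.06 and -3.32. By contrast the MAD was 0.27, 0.29 and 0.27, and the subtelomeric means were 3.33, 3.20 and 3.39. With 1 array per strain, a narrower range on the mutant arrays cannot be told apart from a loss of the mark in arms and flanks.

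Among the named windows, the largest loss of H3K9me2 in mmi1Δ lay on the arm of chromosome 2, where 3 adjoining windows (1473000 to 1477200) had a mean of 2.05 in wild type, 0.80 in mei4 and 0.04 in mmi1Δ. Its middle window (1474500 to 1475700) went from 2.78 to 0.22, a difference of -2.56. Psc3 and Rad21 also lay in that middle window. Psc3 stood at 1.68 in wild type and -0.04 in mmi1Δ, and Rad21 at 2.16 in wild type and -0.05 on the array labelled mmi1Δ. Over the 3 windows Psc3 stood at 1.04 and 1.20 on the wild-type arrays and 0.26 in mmi1Δ. It stood at 1.07 in clr4Δ, 1.17 in dcr1Δ and 0.94 in mmi1Δ rec8Δ, each on 1 array. Lower Psc3 was thus not seen there in clr4Δ, nor to the same extent in mmi1Δ rec8Δ. H3K9me2 was not measured in these strains. In another window of the same chromosome (2202000 to 2203200), H3K9me2 went from 1.59 in wild type to -0.39 in mmi1Δ. Over the 33 stretches of arm windows that reached 1.5 in wild type, and so were picked on that array, the mmi1Δ difference ran from -2.01 to -0.16 with a median of -0.98, and the mei4 difference from -1.25 to 0.10 with a median of -0.82. Some of them, chosen after their values were seen, kept a ratio near 2. A window of chromosome 1 (4908000 to 4909200) had 2.35, 2.09 and 1.97 in wild type, mei4 and mmi1Δ, and a pair of windows on chromosome 3 (274500 to 277200) had 2.87, 2.43 and 2.29.

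In mei4 the largest losses included 4 windows in central cores (-1.79 to -1.51), led by one at centromere 1 (3766500 to 3767700) that went from 4.47 to 2.68. The 10 largest gains in mmi1Δ (1.43 to 1.69) all lay in arm windows that stayed below 0, and 2 of them did not keep their sign with background-subtracted signals. The mean over the central cores was 4.38 in wild type, 3.23 in mei4 and 3.83 in mmi1Δ. The ChIP signal of the cores was 2.06, 1.06 and 2.37, and the extract signal was 0.86 higher in mmi1Δ than in wild type. The repeats differed from wild type by -0.46 in mei4 and -0.43 in mmi1Δ, but by -1.56 and -1.73 with normexp and -1.71 and -2.03 with background-subtracted signals. With MAD scaling the mei4 difference was -0.85.

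Rad21, the mitotic kleisin, was compared to see whether it gives way where Rec8 enters. On the array labelled mmi1Δ it stood at 1.21 in the central cores against 0.49 in wild type, with an extract signal of the cores 0.68 higher, and at 1.92 in the subtelomeres against 0.85, while the repeats had 3.57 against 3.31. The 10 largest differences upward (2.08 to 2.47) all lay in 1 stretch of the right end of chromosome 1 (5539500 to 5555700). The Rad21 arrays also differed in blocks of DNA unrelated to the label. The wild-type array had lost a block of chromosome 1 (2932500 to 2940300), at -6.03 in the extract. The labelled array had lost a block of chromosome 3 (115500 to 116700), at -5.41. Other strain differences therefore cannot be separated from the label. The 10 largest downward differences were in the arms, led by the window of chromosome 2 named above (1474500 to 1475700), at -2.21, with the next at -1.16. At the 345 arm windows where Psc3 reached 1 on its wild-type replicate 1, Rad21 stood at 1.22 in wild type and 0.96 on the array labelled mmi1Δ. That difference of -0.25 changed direction with MAD scaling, to 0.15. The MAD was 0.42 on the wild-type array and 0.29 on the labelled array, and most probes lie in the arms. Such scaling could therefore itself offset a fall at arm sites, so neither value shows whether Rad21 gives way there. The subtelomeric difference of 1.07 was 1.64 with MAD scaling and 0.55 with subtelomeres of 100 kb.

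Rec11, an accessory subunit normally expressed in meiosis, was compared to see where it binds when Rec8 is present in vegetative cells. In mmi1Δ it was higher at the arm sites of cohesin, with a mean of 1.02 against -0.03 in wild type, a difference of 1.05. The 10 largest differences upward (2.16 to 2.53) all lay in the arms. The top window, on chromosome 2 (4114500 to 4115700), went from -0.56 to 1.97. The largest downward difference, -1.62, lay on chromosome 1 (1665000 to 1666200). Its means over the centromere domains were not higher. The central cores stood at 0.00 against 0.28, with an extract signal 0.32 higher and a ChIP signal that differed by -0.02. The repeats stood at 0.13 against 0.50, and the flanks at -0.07 against 0.03. Single windows went the other way, such as a flank window at the left edge of centromere 2 (from 1597500), chosen after its values were seen, at 1.87 against 0.27.

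**Figure D3:**
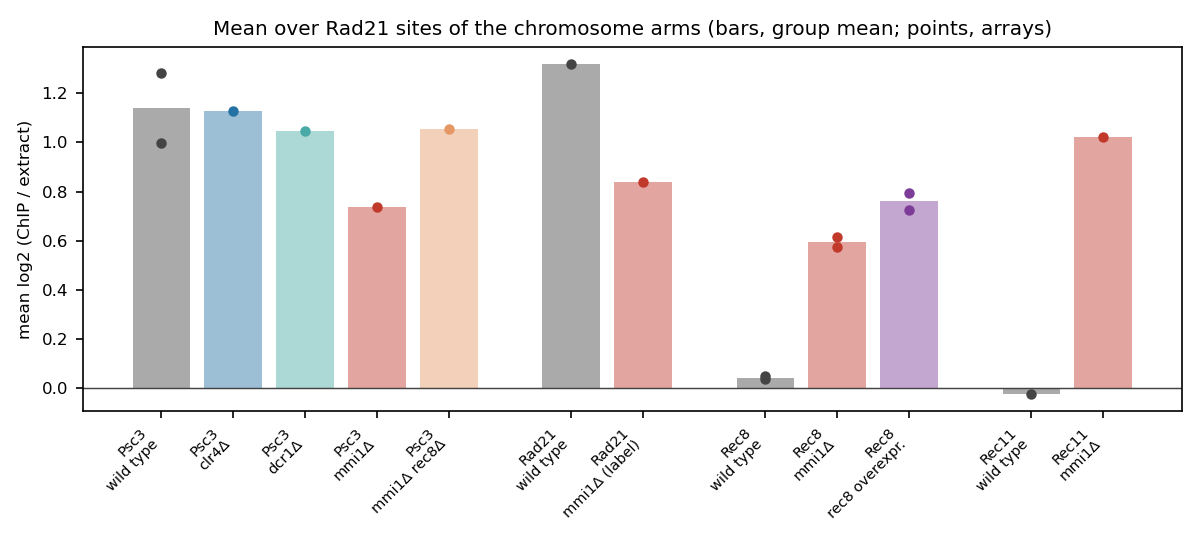
Mean log2 ratio of ChIP over extract (vertical axis) over the 518 arm windows where wild-type Rad21 reached 1, for the cohesin groups (horizontal axis), with bars for group means and points for arrays. Rec8 and Rec11 stand at 0.04 and -0.03 in wild type and at 0.59 and 1.02 in mmi1Δ; the Rad21 values are biased because the sites were picked on its wild-type array.

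The changes in mmi1Δ (for Rad21, on the array so labelled) were also compared between subunits across windows, which are not independent replicates. Over 8326 windows the Rec8 and Rec11 changes had a Spearman correlation of 0.72 (Pearson 0.69), and of 0.77 (0.81) over the 7834 arm windows. The Rec8 change ran against the Psc3 change at -0.54 (Pearson -0.32) and against the Rad21 change at -0.42 (Pearson -0.30). Those negative values depended on the scale of the arrays. With MAD scaling they were -0.046 and -0.035, while Rec8 and Rec11 stayed at 0.67. Altogether 6 pairs of subunits were compared. The Psc3 and Rad21 changes correlated at 0.65, and the other pairs, Psc3 with Rec11 and Rad21 with Rec11, at -0.62 and -0.51. Pairs without Rec8 were not run with MAD scaling, so their dependence on the scale of the arrays is not known. The Psc3 and Rad21 sets share a slide.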

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

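All tests in this part were chosen after the results were seen. No group held 4 to 10 arrays, so no array was tested against the rest of its group.

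Blocks of DNA were missing from the extract of some arrays without matching a gene named in the labels. A block of 27 probes on chromosome 1 (2932500 to 2940300) was lost from the Psc3 dcr1Δ and the wild-type Rad21 arrays, at -7.67 and -6.03 relative to the other arrays. A block of 14 probes on chromosome 1 (3740100 to 3744000), in the left flank of centromere 1, was lost from both rec8 overexpression arrays, at -7.79 and -7.67. A block of 5 probes on chromosome 3 (115500 to 116700) was lost from 9 arrays, at -9.98 to -5.41, among them wild-type and mutant arrays.

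The extract channel, which the comparisons use only as the denominator, was higher in the central cores on every mmi1Δ array with a wild-type array on its slide, by 0.86 for H3K9me2, 1.07 for Psc3, 0.68 for the Rad21 array labelled mmi1Δ, 1.27 and 1.31 for Rec8 and 0.32 for Rec11. In 4 pairs of groups without the label that share a slide the differences had a root mean square of 0.15 and a 95% limit of 0.42, which argues against a slide effect or a chance difference between extracts on the first 5 arrays, from 0.68 up, and leaves it open for Rec11 at 0.32. A bias of dim probes would raise arm probes of the same extract signal as much, and the highest such difference was 0.17 on the first 5 arrays, while for Rec11 it was 0.10 and the bias stays open, because the gap between cores and dim probes was no larger than the highest on arrays without the label, 0.27. More Rec8 in the cores alone would raise the extract under rec8 overexpression too, where the mean difference was 0.22 against 1.29 for Rec8 in mmi1Δ, further apart than that limit. On the mmi1Δ rec8Δ array, with no wild-type array on its slide, the core extract was 0.19 above the wild-type Psc3 mean. Its dim arm probes stood at -0.41. The Psc3 arrays of clr4Δ and dcr1Δ, also without a wild-type array on their slide, had core values of -0.73 and -0.62. Such values mix slide and strain, so they cannot show whether the rise was absent without Rec8. A change of the core chromatin may be the source, but this and any need for Rec8 besides the loss of Mmi1 stay open. So do the copy number of the core DNA and a preparation common to the mmi1Δ extracts.

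H3K9me2 in the wild-type central cores stood at 4.38 against 5.12 in the repeats, although central cores are known to carry CENP-A chromatin, with a ChIP signal of 2.06 against 5.93 and an extract signal of the cores of -2.23. Arm probes as dim in the extract had a median of 0.25, with a 90th percentile of 1.22, which argues against a bias of dim probes. The 33 core probes without a repeat mark had a mean of 4.52 with an SD of 0.33, which argues against hybridisation of repeat copies, as far as the marks are complete. Background-subtracted signals gave 4.48. The processed signals are themselves background-subtracted by the same software, so this value cannot show whether background was left in them, and that stays open. Fragments that reach in from the neighbouring repeats would carry Psc3 in as well, and leave far less H3K9me2 mid-core. Wild-type Psc3 stood at 4.02 ± 0.04 (SD, n = 2) in the repeats and 0.13 ± 0.02 in the 33 unmarked core probes. In the core of centromere 2, H3K9me2 was 4.33 to 4.57 in the middle windows (starts 1623000 to 1627500). Its outermost windows had 4.51 and 4.88. These values argue against such fragments as the main source. The antibody and a poor recovery of cores in the extract may each contribute and stay open, and no biological explanation was tested.

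On the Rad21 array labelled mmi1Δ the extract signal of the mmi1 block was -1.18, where the other 6 labelled arrays had lost it. A swap with the wild-type Rad21 array would show the loss there, and that array stood at -0.04. Admixture of DNA from cells that keep the block of 5 probes on chromosome 3 would leave that block as incompletely lost, and it was at -5.41. A deletion of another extent would leave some probes near 0 or fully lost, and the highest of the 6 single probes was at -1.14. Admixture with cells that lack the chromosome 3 block but keep mmi1, as 3 wild-type arrays do, may be the source and stays open. An equal share of such cells in both channels would lower both alike, and the ChIP signal of the mmi1 block was lower than the extract signal, at -2.74.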

How the results depend on the processing

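Centring on arm probes, leaving out repeat-marked probes and using background-subtracted signals were chosen after the data were seen, and the other alternatives were not. Of 352 values of the 36 main results under an alternative, 244 stayed within the replicate spread, or within 1.5 times a count, 106 moved and 2 changed direction. The 133 named windows of the tested comparisons kept direction and call in 1450 cases, lost the call in 101 and changed direction in 2. The 582 values of the named windows of 1 array against 1 stayed within the spread in 453 cases, moved in 127 and changed direction in 2. These totals include the series value table for H3K9me2, which repeats the scanner values and so could hardly move a result. Except where named below, the cause was not tested.

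With MAD scaling, which gives all arrays of a target one scale, the window count was 136 for Rec8 in mmi1Δ against rec8 overexpression. For Psc3 it was 49 for dcr1Δ, 305 for mmi1Δ, 58 for mmi1Δ rec8Δ against wild type and 220 against mmi1Δ. The difference for rec8 overexpression against wild type was 1.96 in the cores and 1.63 in the repeats, and for mmi1Δ against overexpression -0.42 in the cores and -0.38 in the flanks. It was -1.82 in the subtelomeres for Psc3 in clr4Δ, 4.67 in the cores for Psc3 in mmi1Δ, -3.77 in the cores for mmi1Δ rec8Δ against mmi1Δ, -0.85 in the repeats for H3K9me2 in mei4, 1.07 in the cores and 1.64 in the subtelomeres for Rad21, and 0.92 at the arm sites for Rec11. In all, 2 differences changed direction, to 0.031 for Psc3 in mmi1Δ at the arm sites and 0.15 for the Rad21 array labelled mmi1Δ at the Psc3 sites. The correlation of the Rec8 change was -0.046 with Psc3, -0.035 with Rad21 and 0.67 with Rec11. Of the windows at the end of chromosome 3 higher in mmi1Δ rec8Δ than in mmi1Δ, those at 3000 and 15000 changed direction, to -0.41 and -0.014.

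With normexp the count for Psc3 in dcr1Δ was 0 by limma (240 windows below an unadjusted p of 0.05). Differences were 0.73 at the arm sites for Rec8 in mmi1Δ, 2.08 in the cores and 2.52 in the repeats for rec8 overexpression, -0.31 in the cores and -0.59 in the flanks for mmi1Δ against overexpression, -3.94 in the repeats, -2.19 in the subtelomeres and -2.33 in the mating-type region for Psc3 in clr4Δ, and -0.67 in the repeats for dcr1Δ. They were 3.74 in the cores for Psc3 in mmi1Δ, -3.02 for mmi1Δ rec8Δ against mmi1Δ, -1.56 and -1.73 in the repeats for H3K9me2 in mei4 and mmi1Δ, 1.19 in the subtelomeres and -0.30 at the Psc3 sites for Rad21 and 1.19 at the arm sites for Rec11.

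With the median over probes the count was 44 for Psc3 in dcr1Δ and 44 for mmi1Δ rec8Δ against wild type. Differences were -0.40 in the flanks for Rec8 in mmi1Δ against overexpression, -3.93 in the repeats, -2.002 in the subtelomeres and -2.46 in the mating-type region for Psc3 in clr4Δ, -2.38 in the cores for mmi1Δ rec8Δ against mmi1Δ and 1.47 in the subtelomeres for Rad21.

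Without repeat-marked probes, which left 7 of 219 probes in the repeats and 33 of 102 in the cores, the counts for Psc3 were 93 for clr4Δ, 15 for dcr1Δ, 8 for mmi1Δ, 15 for mmi1Δ rec8Δ against wild type and 26 against mmi1Δ. Differences were 2.05 in the cores and 0.67 in the repeats for Rec8 in mmi1Δ, 1.95 in the repeats for rec8 overexpression, -2.71 in the repeats, -1.52 in the subtelomeres and -2.81 in the mating-type region for Psc3 in clr4Δ, -2.34 in the cores for mmi1Δ rec8Δ against mmi1Δ and 0.83 in the subtelomeres and -0.28 at the Psc3 sites for Rad21. Background-subtracted signals gave counts of 0 for Psc3 in dcr1Δ by limma (367 below an unadjusted p of 0.05) and 15 for mmi1Δ rec8Δ against wild type, and differences of -1.71 and -2.03 in the repeats for H3K9me2 in mei4 and mmi1Δ. With them the H3K9me2 windows of mmi1Δ on chromosome 3 at 780000 and on chromosome 2 at 1816500 changed direction, to -0.015 and -0.026. Centring on arm probes gave 0 windows for Psc3 in dcr1Δ by limma (467 below an unadjusted p of 0.05).

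Fits changed the counts as well. With the replicate number as a block, which takes up the pairing by antibody clone, 748 windows passed for Rec8 in mmi1Δ against overexpression. The joint fit of the Psc3 and Rec8 arrays gave 564 for clr4Δ, 152 for dcr1Δ, 96 for mmi1Δ rec8Δ against wild type and 73 against mmi1Δ. Leaving out each replicate in turn gave 691 to 1070 windows for Rec8 in mmi1Δ against wild type, 1330 to 2417 for rec8 overexpression and 214 to 546 between them, with core differences of 2.45 to 3.03 for overexpression and -1.36 to -0.78 between them, and repeat differences of 2.09 to 2.48 for overexpression. For Psc3 it gave 1260 to 1327 for clr4Δ, 573 to 1140 for dcr1Δ, 485 to 609 for mmi1Δ and 889 to 949 for mmi1Δ rec8Δ against wild type. There the lone wild-type array is assumed to vary like the Rec8 groups, whose spread between replicates was the only one left. In the mating-type region the clr4Δ difference was -2.24 to -1.94 without either wild-type array, and -2.24 against the wild-type array of the same submission batch. At the arm sites the difference for Psc3 in mmi1Δ was -0.55 to -0.26 without either wild-type array, and -0.55 against the array of the same batch.

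Other definitions moved values by construction. H3K9me2 reached 0.5 in 1304, 1051 and 1021 windows of wild type, mei4 and mmi1Δ, and 1.5 in 318 windows of mei4 and 329 of mmi1Δ. With subtelomeres of 100 kb the difference was -1.16 for Psc3 in clr4Δ and 0.55 for Rad21. Over arm windows alone the correlation of the Rec8 change was -0.59 with Psc3, -0.47 with Rad21 and 0.77 with Rec11.

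At least 99.9% of spots were well above background. Still, normexp and background-subtracted signals moved the H3K9me2 differences in the repeats and the dcr1Δ count, as given above. Both settings start from signals without the software's dye normalization, so background and dye cannot be told apart there. The dcr1Δ count was also 0 by limma with centring on arm probes, which leaves background as it is. A slide block was not run for Psc3, where no residual degrees of freedom remain, and for Rec8 it is the replicate block. The value table of the series was run as a source only for the H3K9me2 results, because columns of other groups do not match the scanner values. The match of probe sequences to the reference and the centring on arm genes were replaced by repeat marks and arm probes, because the array's build is not that of the reference. The gene lists, with their estimated correlation, and the intergenic classes were not run for the same reason.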

Other observations

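The regions described in this part were chosen after their values were seen, and no further tests were run on them. The stretch of chromosome 1 spans the subtelomeric windows there that limma called lower for Psc3 in mmi1Δ rec8Δ than in wild type. The low Psc3 value of that array in the stretch therefore follows from the choice.

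At the right end of chromosome 1 a stretch of 64 probes (5538000 to 5557200) had H3K9me2 and Psc3 but little Rad21 in wild type. H3K9me2 stood at 5.15 in wild type, 4.97 in mei4 and 5.02 in mmi1Δ. Psc3 stood at 3.14 and 2.74 on the wild-type arrays, 3.00 in dcr1Δ and 3.23 in mmi1Δ, but at 0.90 in mmi1Δ rec8Δ and 0.03 in clr4Δ. Rad21 stood at 0.35 in wild type and 2.53 on the array labelled mmi1Δ. Rec8 lay between -0.18 and 0.23 on its 6 arrays, and Rec11 at -0.27 and -0.51. The extract signal of the stretch was between -1.27 and 0.01, so the DNA was present on all arrays.

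The 10 highest windows of Rec8 in wild type and 6 of the 10 highest of Rec11 lay at the ends of chromosome 3. The means over these ends, 0.36 ± 0.11 (SD, n = 2) for Rec8 and 0.16 for Rec11, were below those of the telomere clones, 0.58 ± 0.10 (SD, n = 2) and 1.40, and of the pericentromeric repeats. The highest window of Rec11 (3000 to 4200) stood at 1.98, and that of Rec8 (13500 to 14700) at 1.34. The mean of Psc3 in clr4Δ was 0.60 over these ends against 0.69 in wild type, unlike the subtelomeres of chromosomes 1 and 2. Some single windows of these ends were lower in clr4Δ all the same. The telomere clones had Psc3 at 1.81 ± 0.36 (SD, n = 2) in wild type, 0.25 in clr4Δ, 2.43 in dcr1Δ and 2.97 in mmi1Δ rec8Δ. The mitochondrial genome, which holds no nucleosomes, stood at -4.65 for H3K9me2 and -2.97 ± 0.27 (SD, n = 2) for Psc3 in wild type.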
